A study of Homo sapiens with 6 samples.

How the data were processed

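RNA was profiled in the human neuroblastoma line IMR32 on 6 Affymetrix HG-U133 Plus 2.0 arrays, 3 from cells given 0.1% DMSO and 3 from cells given 118 µM teriflunomide for 24 h. Per the labels' protocols, treatment began 12 h after seeding, total RNA was extracted and the target was labelled with biotin. The deposited values are log2 expression intensities, 1 per probe set and array, made by the authors with GCRMA per the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, brings the arrays to a common distribution and summarises the probes of each probe set. Its version and settings are not given in the sources used here. A log2 unit is a doubling of intensity, so differences between groups are log2 fold changes.

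The background step decides what dim probe sets can show. Each array had a lowest value of 2.18, and between 33.8% and 34.2% of its probe sets sat at that value. A fold change that starts or ends near this floor depends on the background model, and its size is less certain than that of a bright gene. Array medians lay between 2.63 and 2.66 and 75th percentiles between 7.87 and 7.92. Arrays give no read depth; the number of arrays, 3 per group, limits the precision.

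The table held 54675 probe sets, of which 62 were controls. Names came from the platform annotation: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Of the named probe sets, 41043 were matched by gene identifier to a reference gene table of assembly GRCh38.p14, used for names alone, and 0 symbols needed updating. Probe sets with several symbols or none were left out of the gene tests. No genome build was tied to the arrays in the sources used here, so no coordinates are given. A probe set was tested when its value lay at or above its array's median on at least 3 of the 6 arrays, a filter blind to treatment that 27290 probe sets passed. Of several probe sets of a gene, the one with the highest mean over the 6 arrays stood for the gene, which gave 11998 genes.

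Teriflunomide was compared with DMSO by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the deposited log2 values, no covariates and no further normalization. All p-values are two-sided, and adjusted p-values follow Benjamini-Hochberg over the 11998 genes, with a threshold of 0.05. Where probe sets were tested singly, the adjustment was over the probe sets tested. The error given with a log2 fold change is limma's standard error (SE). Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists tested, and lists with fewer than 5 tested members were described without a test. Camera asks whether a list's genes rank above or below the other genes. Where the correlation was estimated instead, camera took p from the residual degrees of freedom, 4 here. That alone makes its p larger than at the preset. Of the members of the 25 lists, 92 were below the filter and 66 had no probe set of a single symbol here. The array's control probe sets were compared by exact permutation tests of the group means, which with 3 arrays against 3 cannot give a p below 0.1. Python 3.11.15 was used for reading the table and drawing.

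The groups, the tests, the filter, the 25 gene lists, the first set of alternatives named below and the rule for named genes were fixed before the data were examined. The rule took the 10 genes that rose most and the 10 that fell most among those past the threshold whose arrays did not overlap between groups. It also took, per list, the 2 members past the threshold with the largest change and the largest change in the opposite direction. Of 9 further genes fixed by name, 1 was not analysed here. The rule gave 86 tested genes, 38 of them with 2 or more tested probe sets. Any other gene is named as chosen after its values were seen.

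The fit was tested on simulated data: values for 11998 genes with the real means and spread, a few of them changed by known amounts. Of the genes changed by log2 0.5, 58.2% were called, against 95.5% of those changed by log2 1 and 98.5% of those changed by log2 2, with 10 false calls among 11798 unchanged genes. With so few genes changed, the adjusted threshold was stricter than in the real data, where 58.6% of genes passed. These rates therefore do not describe the share of real changes that was called. Camera called the 1 list that had been shifted and 0 of the 23 others. The simulated genes varied independently of each other, so this could not show how camera fares when the genes of a list are correlated.

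The first set of alternative settings was no filter, a filter at the 75th percentile, centring of the arrays, quantile normalization, the mean of a gene's probe sets, preference for probe sets with a plain suffix, trended and robust eBayes, array weights, the replicate number as a block, leaving out each array in turn, camera with an estimated correlation, and fry. A further pair was chosen after seeing the data: values under log2 5 raised to 5, and arrays centred on the poly-A spike controls.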

Results

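Gene expression was measured in IMR32, an established human neuroblastoma cell line that carries an amplified MYCN gene. Cells received 0.1% DMSO as the control, or 118 µM teriflunomide, for 24 h. Whether the teriflunomide wells also held DMSO was not stated, so the fold changes may include a difference in DMSO. Teriflunomide inhibits dihydroorotate dehydrogenase (DHODH), the mitochondrial enzyme of de novo pyrimidine synthesis. Each group held 3 arrays described as biological replicates. Whether the replicates came from separate cultures was not stated, so the p-values measure only the spread between these arrays, which may be technical. Across all probe sets, which are not independent replicates, Pearson's r between arrays was 0.998 to 0.999 within the DMSO group and 0.999 within the teriflunomide group. Between the groups it was 0.989 to 0.990. No arrays held identical values.

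The comparison asked how expression in these cells differed between teriflunomide and DMSO; the activity of DHODH was not measured here. After teriflunomide, 31 of the 32 tested genes of amino acid supply and the integrated stress response rose, as did 17 of 21 genes of oxidative stress defence. Of ribosome biogenesis genes, 26 of 30 fell, as did 26 of 36 mitosis genes. As lists, these passed camera with a preset correlation but not with an estimated one (adjusted p = 0.134 for the first 3 and 0.331 for mitosis). The estimated run also rested on 4 residual degrees of freedom, so its larger p-values do not come from correlation alone. Of 11998 genes tested with limma, 3560 were higher and 3471 lower with teriflunomide at an adjusted p under 0.05, and 4967 did not pass. At least 2-fold, 629 genes were higher and 543 lower. The arrays of the groups did not overlap for 8039 genes, or 67%, where chance gives 10%. The median log2 fold change over all genes was 0.0015. GCRMA brings the arrays to a common distribution, so a shift common to all genes would not show in these values. The plot of log2 fold change against mean intensity shows these genes.

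**Figure D1:**
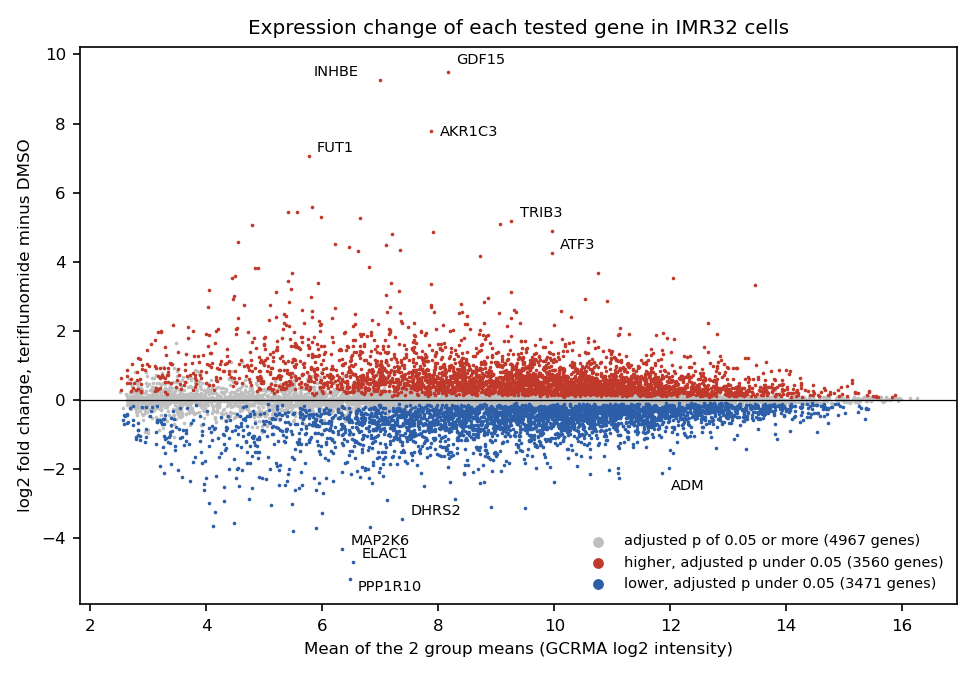
Each point is 1 of 11998 genes in IMR32 cells, with the mean of both group means (GCRMA log2 intensity) on the x axis and the log2 fold change, teriflunomide minus DMSO, on the y axis. Red points are the 3560 genes that were higher and blue points the 3471 that were lower at an adjusted p under 0.05, grey points are the other 4967 genes, and 11 named genes carry their symbols.

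GDF15, a secreted cytokine induced by cellular stress, rose most, from 3.43 ± 0.41 to 12.91 ± 0.13 (log2 mean ± SD, n = 3 per group). Its log2 fold change was 9.48 (SE 0.22, limma adjusted p = 1.66e-05). INHBE, which encodes an inhibin beta subunit, rose by 9.25 (SE 0.12). AKR1C3, an aldo-keto reductase, rose by 7.77 (SE 0.40), and its near-identical relatives make its identity on a probe set uncertain. FUT1, a fucosyltransferase, rose by 7.05 (SE 0.05). The other 6 of the 10 largest increases were GPNMB (5.58), LAMP3 (5.45), KLHDC7B (5.45), CHAC1 (5.30), ALDH1L2 (5.26) and TRIB3 (5.17). TRIB3, a pseudokinase induced by ATF4 and CHOP, started well above background and rose from 6.68 ± 0.21 to 11.84 ± 0.13, a 35.9-fold change. The other 9 had DMSO means under log2 5, near the floor of the arrays. With values under log2 5 raised to 5, the increases of the 10 ranged from 3.13 to 7.91. GPNMB then stood at 3.61, LAMP3 at 3.28 and KLHDC7B at 3.13. SLC7A11, outside the 10 and above log2 5 on every array, rose by 5.10, so membership of the 10 depends on the floor.

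PPP1R10, which encodes a nuclear regulatory subunit of protein phosphatase 1, fell most, from 9.06 ± 0.09 to 3.88 ± 0.14 (log2 mean ± SD, n = 3 per group). Its log2 fold change was -5.18 (SE 0.09, limma adjusted p = 7.81e-06). ELAC1, a tRNA-processing enzyme, changed by -4.69, and MAP2K6, a kinase upstream of p38, by -4.32. The remaining 7 were TMEM169 (-3.79), ADAMTS8 (-3.72), LNP1 (-3.67), HOXD10 (-3.64), RORB (-3.55), DHRS2 (-3.45) and AQP1 (-3.28). Of these 10, 9 had teriflunomide means under log2 5. With values under log2 5 raised to 5, their changes ranged from -0.94 to -4.06. The moves were large for TMEM169 (to -2.39), RORB (to -1.25) and HOXD10 (to -0.94). MAP2K6 changed by -1.44 where a probe set with a plain suffix was preferred, a dim one with a mean of log2 4.37.

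Of the 32 tested genes of the amino acid and integrated stress response list, 31 rose, 25 of them at least 2-fold, and the median log2 fold change was 2.15. The list holds targets of ATF4, a transcription factor translated when eIF2α is phosphorylated. CHAC1, a glutathione-degrading enzyme, rose by 5.30 (SE 0.31) and ALDH1L2, of mitochondrial folate metabolism, by 5.26 (SE 0.19). DDIT3, which encodes CHOP, rose by 4.89, ASNS (asparagine synthetase) by 3.32 and ATF4 itself by 1.10. These 3 were chosen after their values were seen, as was CBS, of cysteine synthesis, the member that did not pass, at 0.06. Camera gave the list an adjusted p of 5.25e-16, and an adjusted p of 0.134 with an estimated correlation.

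Of 21 NRF2 and oxidative stress genes, 17 rose and 2 fell, with a median log2 fold change of 0.96. SLC7A11, the cystine transporter subunit and also a member of the amino acid list, rose by 5.10 (SE 0.11), and ABCC1, a glutathione conjugate exporter, fell by 0.29 (SE 0.06). HMOX1 (haem oxygenase), chosen after its value was seen, rose by 4.85. Camera gave this list an adjusted p of 1.22e-05, and an adjusted p of 0.134 with an estimated correlation. Of 20 immediate early genes, 15 rose and 1 fell, with a median of 0.63. KLF4 rose by 4.48 (SE 0.49) and ATF3, which the amino acid list also holds, by 4.25 (SE 0.06), while SRF fell by 0.54. Camera gave this list an adjusted p of 0.000267, and an adjusted p of 0.134 with an estimated correlation. The correlation estimated for its members was -0.051, below the preset 0.01, so correlated members do not explain that weaker result. The 4 residual degrees of freedom of that run make its p larger.

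Of 26 p53 targets, 15 rose, 3 fell and 8 did not pass, with a median log2 fold change of 0.47; adjusted over the list alone, 16 rose and 3 fell. Besides GDF15, SESN2 rose by 3.37 (SE 0.11), and both are also known to respond to ATF4 or CHOP (SESN2 is in the amino acid list too). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.40 (SE 0.08). XPC, a DNA damage recognition gene, fell by 0.91. MDM2, the p53 ubiquitin ligase, stood at -0.02 (SE 0.10, adjusted p = 0.860 by limma) and was chosen after its value was seen. Camera gave the list an adjusted p of 0.00392, and an adjusted p of 0.331 with an estimated correlation.

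Of 30 ribosome biogenesis genes, 26 fell, 1 rose and 3 did not pass, with a median log2 fold change of -0.73. UTP20, of the small subunit processome, changed by -1.70 (SE 0.15) and NOP16, a nucleolar protein gene, by -1.39 (SE 0.04, and -0.87 as the mean of its probe sets). That mean includes a dim NOP16 probe set (mean log2 2.90) at 0.22, while the other bright one changed by -1.44. UBTF, a transcription factor of RNA polymerase I, rose by 0.48 on the probe set used and changed by -1.52 on another, so its direction is not settled. Camera gave the list an adjusted p of 1.57e-07, and an adjusted p of 0.134 with an estimated correlation. Of 24 ribosomal protein genes, 7 rose (5 adjusted over the list alone) and 0 fell, by small amounts such as 0.26 for RPL3 and 0.15 for RPL32, whose call was lost with centring on poly-A spikes. Their median was 0.07 (0.03 to 0.08 over the scalings tried), with a camera adjusted p of 0.0796 that became 0.000705 with no filter, 0.0225 with trended and robust eBayes and 0.00773 with values under log2 5 raised to 5, and an adjusted p of 0.331 with an estimated correlation.

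Cell cycle genes had smaller medians. Of 36 mitosis genes, 26 fell, 1 rose and 9 did not pass, with a median log2 fold change of -0.28. HMMR, a spindle-associated gene, changed by -0.85 (SE 0.11) and ASPM, of the spindle poles, by -1 (SE 0.07), while its other probe sets stood at -1.10 and, not past the threshold, 0.12. NEK2, a centrosomal kinase, rose by 0.17, a call lost when any of 4 of the arrays was left out, with no filter and with centring on poly-A spikes. Camera gave mitosis an adjusted p of 1.29e-05, and an adjusted p of 0.331 with an estimated correlation. Of 37 replication and S phase genes, 20 fell, 3 rose and 14 did not pass, with a median of -0.21. CCNE1 (cyclin E1) changed by -0.85 and POLA1 (DNA polymerase alpha) by -0.84, while PRIM1, a primase subunit, rose by 0.50. Camera gave this list an adjusted p of 0.00188, and an adjusted p of 0.291 with an estimated correlation.

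**Figure D2:**
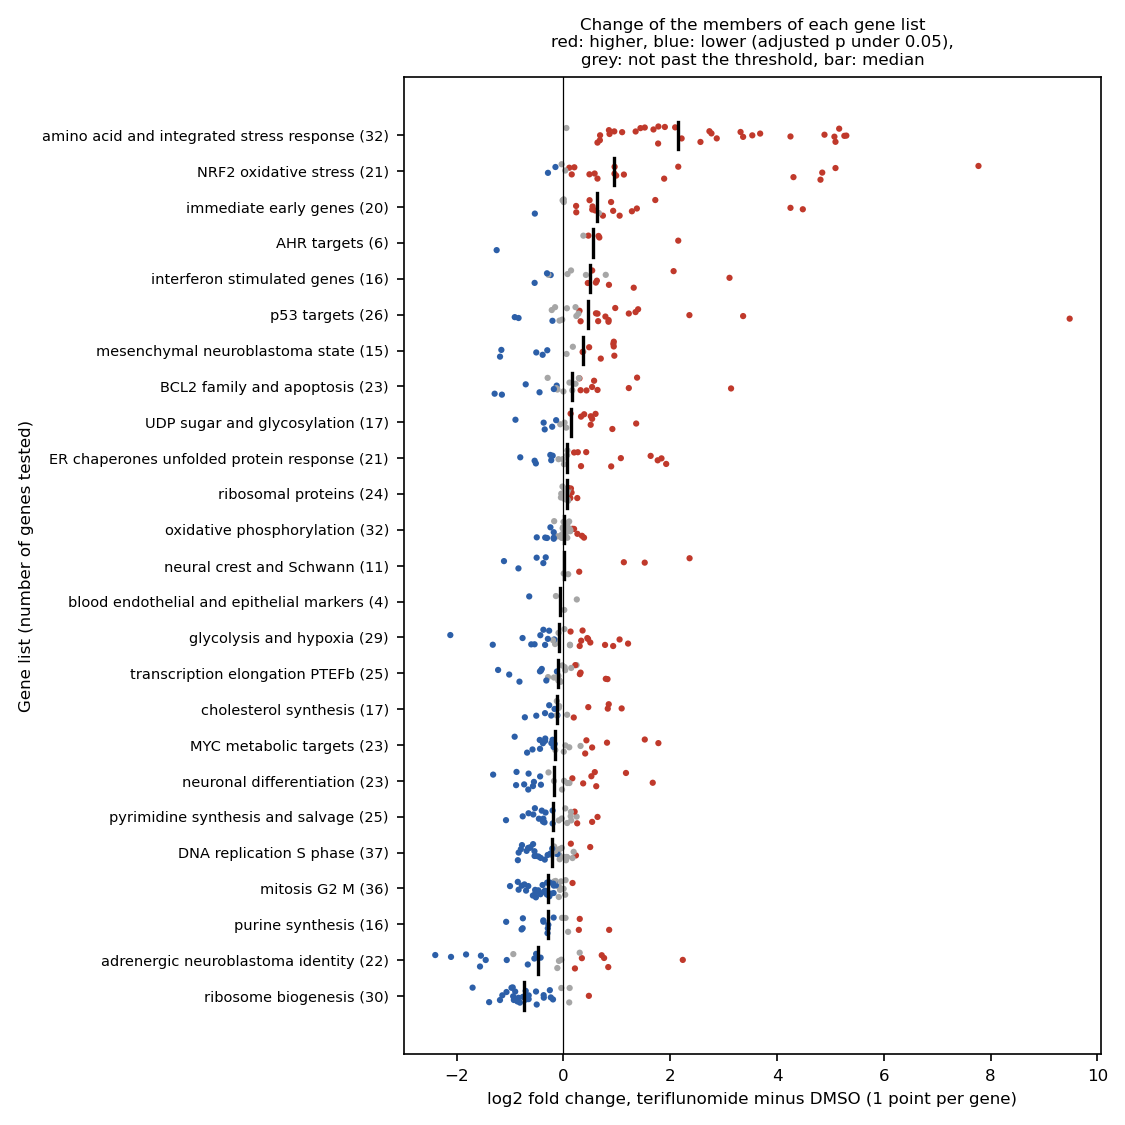
Each point is the log2 fold change (teriflunomide minus DMSO) of 1 tested gene, grouped by the 25 gene lists on the y axis, with the number of genes tested in brackets. Red and blue points were higher or lower at an adjusted p under 0.05, grey points were not, and black bars mark medians, which run from 2.15 for the amino acid and integrated stress response to -0.73 for ribosome biogenesis.

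In the pathway of the drug's target, 13 of 25 pyrimidine synthesis and salvage genes fell, 4 rose and 8 did not pass, with a median log2 fold change of -0.20 (camera adjusted p = 0.227). UMPS, the enzyme after DHODH in the pathway, fell from 11.99 ± 0.04 to 11.34 ± 0.04 (log2 mean ± SD, n = 3 per group), a change of -0.65. Another bright UMPS probe set changed by -0.82, and a dim one with a plain suffix (mean log2 4.35) by -0.36. CAD, which carries the first steps, rose by 0.54 (SE 0.03), as did RRM2B by 0.64, and CMPK2 changed by -0.76. DHODH itself was dim, 3.89 in DMSO and 2.81 with teriflunomide, and its change of -1.08 (SE 0.25) became 0 with values under log2 5 raised to 5. Of 16 purine synthesis genes, 10 fell and 3 rose, with PFAS at -1.07 and ADSS1 at 0.86 (camera adjusted p = 0.0898, 0.0226 with no filter, and adjusted p = 0.331 with an estimated correlation). Of 17 UDP-sugar and glycosylation genes, 9 rose and 5 fell, with GFPT1, the entry enzyme of hexosamine synthesis, at 1.36, GALT at 0.92 (0.75 and 0.32 as means of their probe sets) and UGCG at -0.90 (camera adjusted p = 0.380). The other GALT probe set was dim (mean log2 4.955) and did not pass at -0.28.

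Neuroblastoma identity genes moved in both directions. Of 22 adrenergic genes, 11 fell, 7 of them at least 2-fold, and 6 rose, with INSM1 at -2.40 and SCG2 at 2.24 (camera adjusted p = 0.215). SOX11 (-2.10) and ALK (-1.56), both chosen after their values were seen, fell too. MYCN, the amplified oncogene, fell from 15.11 ± 0.02 to 14.69 ± 0.08 (log2 mean ± SD, n = 3 per group). Of 15 mesenchymal genes, 7 rose (9 adjusted over the list alone) and 5 fell, with FN1 at 0.95, SNAI2 at -1.19 and THY1 at -1.16 (camera adjusted p = 0.225). Of 23 neuronal genes, 10 fell and 7 rose, with NEFL at -1.32 and PRPH at 1.67 (camera adjusted p = 0.380). Of 11 neural crest genes, 4 rose and 5 fell, with MSX2 at 1.52 and SOX9 at -1.11 (camera adjusted p = 0.866). NGFR, at 2.36, did not pass with values under log2 5 raised to 5. The neural crest median was 0.006 and its mean 0.20, while camera's direction was down.

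Of 21 endoplasmic reticulum chaperone and unfolded protein response genes, 10 rose and 6 fell, with HERPUD1 at 1.93, ERN1 at 1.84 and SDF2L1 at -0.81 (camera adjusted p = 0.225). Of 23 BCL2 family and apoptosis genes, 9 rose and 6 fell (camera adjusted p = 0.474). The pro-apoptotic genes HRK and BMF rose by 3.14 and 1.38 (BMF by 0.44 with values under log2 5 raised to 5), and BCL2L11 changed by -1.29 on the probe set used and 1.14 on another. Of 35 interferon-stimulated genes, 16 were tested. Of these, 8 rose and 3 fell, with IFI35 at 3.11, ISG20 at 2.06 and USP18 at -0.54 (camera adjusted p = 0.0898). Among those not tested, MX1, IFIT2 and IFIT3, chosen after their values were seen, lay at the lowest value of the arrays in both groups. IFI35 was dim in DMSO, and its change was 1.75 with values under log2 5 raised to 5. The USP18 call was lost when any of 4 of the arrays was left out, with no filter and with values under log2 5 raised to 5. Of 15 aryl hydrocarbon receptor targets, 6 were tested and 4 rose (5 adjusted over the list alone), led by NQO1 at 2.15 (camera adjusted p = 0.117). NQO1 also belongs to the NRF2 and oxidative stress list. CYP1A1, fixed by name, lay at the lowest value of the arrays in both groups, and CYP1B1 went from 3.99 to 2.74, both near the floor, where its change became 0 with values under log2 5 raised to 5.

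Of 23 MYC metabolic targets, 12 fell and 6 rose, with HSPE1 at -0.91, SLC7A5 at 1.78 and SHMT2 at 1.52. SLC7A5 and SHMT2 also belong to the amino acid list. The median was -0.16, the mean 0.04 and camera's direction down (adjusted p = 0.516). Of 29 glycolysis and hypoxia genes, 11 rose and 11 fell, with ENO2 at 1.21, ADM at -2.12 and PDK1 at -1.32 (camera adjusted p = 0.768). Of 32 oxidative phosphorylation genes, 20 did not pass, 7 fell and 5 rose, the largest being NDUFV2 at -0.50 and NDUFB5 at 0.39 (camera adjusted p = 0.866). Of 17 cholesterol synthesis genes, 7 fell and 5 rose, with STARD4 at 1.09, SC5D at 0.85 and SQLE at -0.72. The median was -0.11, the mean 0.04 and camera's direction down (adjusted p = 0.614). Of 25 transcription elongation genes, 8 fell and 5 rose, with CDK12 at -1.22 (-0.66 as the mean of its probe sets) and HEXIM2 at -1.02 (camera adjusted p = 0.380). The CDK12 mean includes dim probe sets with means of log2 2.67 to 3.42, while its bright ones changed by -0.94 to -1.22. HEXIM1, an inhibitor of P-TEFb, rose by 0.83 on the probe set used and changed by -0.69 on another; neither HEXIM1 nor HEXIM2 passed with the mean of their probe sets. Of the markers of blood, endothelial and epithelial cells, 4 of 22 were tested, 1 fell (MUC1, -0.64) and 3 did not pass.

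**Figure D3:**
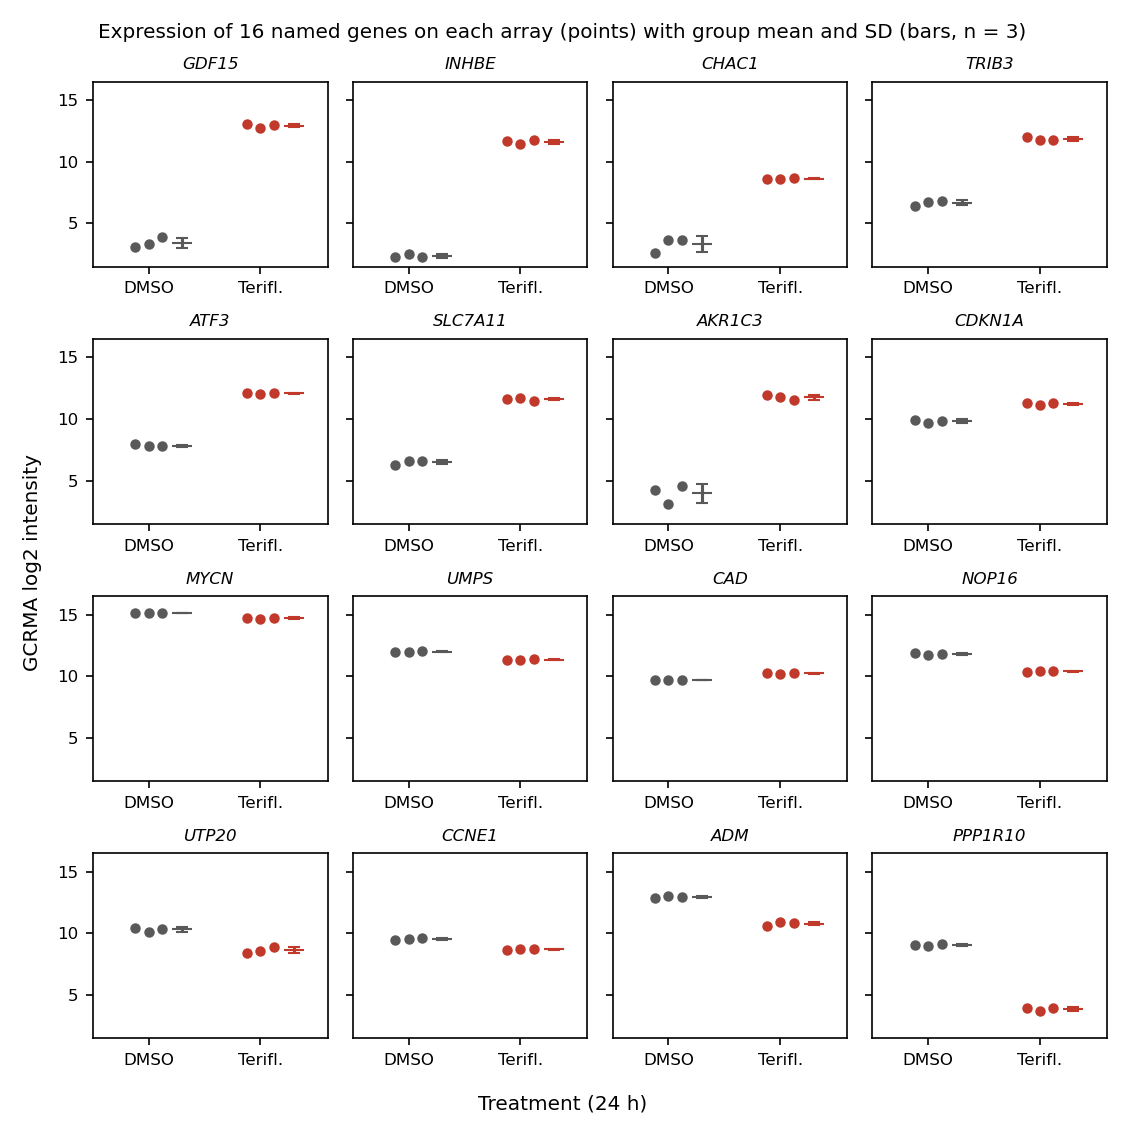
Points are GCRMA log2 intensities of 16 named genes on each of the 3 DMSO and 3 teriflunomide arrays, with the group mean and SD beside them. The arrays of the groups do not overlap for any gene shown, with log2 fold changes from 9.48 for GDF15 to -5.18 for PPP1R10.

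A control probe set measure differed on every teriflunomide array from every DMSO array, and so alongside each gene group above. The ACTB 3' minus 5' signal, a sign of RNA or target length, was 1.36 ± 0.03 in DMSO and 1.62 ± 0.07 with teriflunomide (log2 mean ± SD, n = 3 per group, exact permutation p = 0.1, the smallest this design allows). For GAPDH the same difference was 0.049 and 0.063 (exact permutation p = 0.4). Of 24 lists tested, 4 were called higher and 3 lower by camera with the preset correlation and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.134.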

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

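The test of the amino acid and integrated stress response list was chosen after the result was seen, and the reading of the p53 list test was changed after its result was seen; the splits of the arrays and the brightness test of disagreeing probe sets were set out before their results.

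Signal outside the gene tests was counted as well, with p-values adjusted over the 27290 probe sets that passed the filter. Among 3487 probe sets with no gene symbol here, 175 were higher and 211 lower at least 2-fold with teriflunomide. Among 1068 probe sets with several symbols, 40 were higher and 56 lower. For comparison, of the 11998 genes tested, 629 were higher and 543 lower at least 2-fold.

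The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the 3560 higher, 3471 lower, 629 higher at least 2-fold and 543 lower at least 2-fold genes, 1 split gave as many each time, the real one, and the highest other split gave 0. For the lists called by camera with the preset correlation, counting the larger of both directions in each other split, 5 of the 10 splits gave as many as the real 4 higher and 7 as many as the real 3 lower, the highest other count being 5. Each other split set 2 arrays of a treatment and 1 of the other against the reverse, so part of the treatment difference stayed in it while its spread within groups grew. The other splits are therefore no measure of how many lists or genes are called with no treatment effect.

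The rise of the amino acid and integrated stress response genes was weighed against a general unfolded protein response, which brings up chaperones too. Among 14 tested endoplasmic reticulum chaperones and folding factors, 4 rose and 5 fell, and the highest, HYOU1, reached 0.43 (SE 0.06). The mark for a rise, log2 1, was set after the values were seen. The highest lay below that mark, and the median log2 fold change of the 14 was 0. A mark set with the values known cannot decide the cause. A smaller rise of chaperones stays open. Other genes of that response did rise, HERPUD1 by 1.93, ERN1 by 1.84, EDEM1 by 1.77, XBP1 by 1.63, ATF6 by 1.08 and SEL1L by 0.90 (EDEM1, XBP1, ATF6 and SEL1L chosen after their values were seen), so a response without the chaperones stays open. Activation of ATF4 by nucleotide shortage or by another effect of 118 µM teriflunomide may also underlie the rise, untested here without a uridine rescue or another dose.

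The rise of the p53 targets may come in part from genes that ATF4 and CHOP also induce. Without GDF15, SESN2, TNFRSF10B, PMAIP1 and GADD45A, 10 of the 21 members left were higher and 3 lower, with a camera p of 0.034. The test as first set out would have read this as an argument against shared members as the whole cause. It is left open because camera with an estimated correlation, 0.072 for these members against the preset 0.01, gave a p of 0.21. That run also used the 4 residual degrees of freedom, which raise a p by themselves. How far the correlation itself raised the p of 0.21 was not tested. Whether p53 was active was not tested.

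Of 6081 genes with 2 or more tested probe sets, 50 (0.822%) had probe sets that changed at least 2-fold in opposite directions, such as GSK3B (1.72 and -3.32) and RSF1 (1.22 and -4.18), both chosen after their values were seen. The real split gave 50 such genes, 1 split of 10 gave as many and the highest other, again a mix of treatments, gave 0, too few splits for a share under 0.05. If dim or cross-hybridising probe sets made such genes, they were taken to be rare among bright probe sets with a plain suffix. The share there was 1.004% (14 of 1395), not lower than over all such genes. A plain suffix does not exclude cross-hybridisation, so that explanation stays open. A change in transcript ends or splicing may be involved, but probe positions were not analysed here. The ACTB 3' minus 5' difference also moved with treatment, by 0.264, so unequal RNA or target length stays open.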

How the results depend on the processing

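The alternatives that raised values under log2 5 to 5 or centred arrays on poly-A spikes were chosen after seeing the data. Of 86 named genes, 70 were tested under all 17 alternatives, and 64 of these kept their direction and side of the threshold in each; the other 16 were not tested with the stricter filter. That filter tested 7992 genes and left 378 higher and 304 lower at least 2-fold. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry, which does not compare a list with other genes, called 12 and 8. Leaving out each array gave 3158 to 3312 genes higher, 3059 to 3270 lower, 603 to 640 higher and 506 to 550 lower at least 2-fold, and 4 and 3 lists each time. Named genes reversed with the choice of probe set: UBTF to -0.066 (mean of probe sets) and -1.52 (plain suffix), ASPM to 0.12 (plain suffix) and BCL2L11 to 0.10 (mean). Over all 7031 calls, the mean of probe sets kept 6283, of which 146 had the opposite sign. The plain suffix kept 6588, of which 98 had the opposite sign, and no filter kept 5960. The MYC metabolic list turned to higher with fry (adjusted p = 0.000568). Over the list tests under all alternatives, 424 results kept their direction and side of the threshold, 16 newly passed, 7 no longer passed and 8 changed direction. Besides the MYC list these were lists that passed in neither setting: neural crest with the stricter filter (adjusted p = 0.894), the mean of probe sets (0.832) and fry (0.771), cholesterol synthesis with the mean of probe sets (0.970) and fry (0.473), and oxidative phosphorylation with the mean of probe sets (0.693) and the plain suffix (0.854). The cause was not tested beyond the probe sets' own disagreement. With the mean of probe sets, HEXIM1 (0.07) and HEXIM2 (-0.19) no longer passed. NEK2 lost its call without DMSO replicate 1 (0.158) or 3 (0.157) or teriflunomide replicate 1 (0.149) or 2 (0.151), and USP18 without DMSO replicate 2 (-0.557) or 3 (-0.386) or teriflunomide replicate 1 (-0.5) or 3 (-0.459). Same-numbered arrays of the groups correlated at 0.044, 0.099 and -0.09 in their deviations. For DMSO replicates 1 and 2 the same-numbered array was the best match, while DMSO replicate 3 correlated best with teriflunomide replicate 1 (0.141). Correlations this weak show no clear pairing by number and cannot exclude one. With the replicate block, the count of genes higher with teriflunomide was 3359 and of genes lower with teriflunomide 3282, that of genes higher at least 2-fold 620 and of genes lower at least 2-fold 539, with 4 and 3 lists, 6357 of the 7031 calls were kept, and of the named genes USP18 lost its call. Signal over background limits dim genes: 160 of the 629 genes higher at least 2-fold had DMSO means under log2 5, and 138 of the 543 lower had teriflunomide means under it.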

Other observations

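All gene lists in this part, and the genes named from them, were chosen after the expression values were seen. The tests of the lysosome and autophagy genes, the cytosolic tRNA synthetases and the cleavage and polyadenylation factors were set after their results were seen. The requirement that a list's call hold with an estimated correlation, adjusted over the 5 lists, was added after the values were seen and changed the reading of the lysosome and autophagy test and of the cleavage and polyadenylation test.

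A rise of lysosome and autophagy genes was noticed from GPNMB, LAMP3 and SQSTM1, which were left out of the test. Of 43 other genes, 26 rose, 4 fell and 13 did not pass, with a median log2 fold change of 0.35. Camera gave a p of 6.9e-05 and an adjusted p of 0.000345. With an estimated correlation the p was 0.0323 and the adjusted p 0.162, so the shift of the list stays open. TFEB, a transcription factor of lysosomal genes, rose by 1.94, WIPI1, of autophagosome formation, by 1.98, MAP1LC3B by 1.43 and NEU1, a lysosomal sialidase, by 1.27. TFEB may drive these genes, a hypothesis that was not tested, since neither protein location nor flux was measured.

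Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were looked at by compartment. Of 15 tested mitochondrial synthetase genes, 10 fell, 1 rose and 4 did not pass, with CARS2 at -1.45 and MARS2 at -1.18 (camera direction down, p = 0.00401, adjusted p = 0.01, and adjusted p = 0.198 with an estimated correlation). Among cytosolic synthetases, AARS1 (2.09), CARS1 (1.77) and WARS1 (1.69) rose, but the 12 tested without AARS1, CARS1, SARS1, GARS1 and WARS1 did not pass as a group, with 6 higher and 5 lower. Camera gave them a p of 0.35. The genes left out had the largest increases among the tested cytosolic synthetases. The test of the rest therefore leans against a shift of the whole group and cannot exclude it. The difference between the compartments was not itself tested.

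The tested heat shock genes did not pass as a group. Of 18 listed, HSPA1A and HSPA1B were among those not tested, so a change in them could not be seen here. Of 13 tested, 4 rose and 8 fell, with DNAJB4 at 0.92 and HSPH1 at -0.91. Camera gave them a p of 0.243, with direction down. Of 19 cleavage and polyadenylation factors without PCF11, 10 fell and 2 rose (camera p = 0.045, adjusted p = 0.075, and adjusted p = 0.198 with an estimated correlation), and PCF11, from which the pattern was noticed, stood at -2.15 on the probe set used and at 1 on another. Whether a lower supply of these factors bears on the probe sets of a gene that disagree was not tested.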
